A study of Mus musculus with 6 samples.

How the data were processed

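Bulk RNA sequencing was analysed from lumbar dorsal root ganglia of 6 mice, 3 wild type and 3 labelled as knockouts of the NMDA receptor. The labels give total RNA with a RIN above 8.0 and a stranded mRNA library kit. They number the mice from 1 to 3 in the wild type and from 4 to 6 in the knockout, and give no sex, age, litter or batch. Reads were trimmed with Trimmomatic 0.38, aligned with STAR 2.6.0a and quantified with RSEM 1.3.0 on GRCm38, per the submitters' processing notes. The annotation release and the strand setting of the quantification are not given in the sources used here. The authors deposited 1 table of RSEM values, with expected counts, TPM, FPKM and gene lengths for each library. The file headers only name the expected counts. In RSEM these are estimated counts per gene that are not normalized. RSEM divides reads that match several transcripts, so 27.1 to 27.9% of the detected genes per library had expected counts that were not whole within a tolerance of 1e-09. The deposited TPM values summed to about 1000000 in each library and served only as an alternative. The deposited FPKM values were summed per library and entered no test.

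The table held 36793 gene identifiers, of which 35243 matched a symbol, none of these on chromosome Y or the mitochondrial genome. Symbols, positions and GC content came from GENCODE vM21 on GRCm38. The other 1550 were not placed, and held 0.224 to 0.263% of the counts per library. Total expected counts ranged from 28526704 to 36249163 per library.

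Before groups were compared, each pair of libraries was tested by chi-square over 10258 genes with whole counts and a mean of at least 20. Knockout libraries 5 and 6 had a mean chi-square per gene of 1.15, where sampling noise alone gives about 1, and 0 genes differed at an FDR of 0.05. The other 14 pairs had 13.2 to 104.0 and 3382 to 7317 differing genes. Libraries 5 and 6 were therefore counted as 1 sample by summing their counts, and the comparison was made between 3 wild-type and 2 knockout samples. The design fixed before the data were examined had 6 separate libraries. Counting libraries 5 and 6 as 1 sample was decided after the pair check, and the fixed design was run as an alternative with its counts beside the lead counts. Where simulated libraries came from 1 RNA, the check gave 1.01 and 1 differing gene. Where they came from different RNA, it gave 40.1 and 5388. The spread between the different RNAs was preset and not estimated from these mice. These values therefore reflect that setting and do not show how far apart 2 real animals lie.

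Expected counts were rounded to whole numbers, filtered with filterByExpr and scaled by TMM. They were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with genotype as the only term, two-sided and with Benjamini-Hochberg adjustment at 0.05. Levels are TMM-normalised CPM, counts per 1000000, and errors are SDs over samples. Standard errors of log2 fold changes were derived from the test. Each is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and is approximate at low counts. Nothing in the labels beyond the mouse numbers says how the animals were chosen, so p-values rest on the spread between these samples. That spread is moderated across genes, and 1 of the 2 knockout samples is the sum of libraries 5 and 6. On simulated data with 16548 genes and the depths of the same 5 samples, 65 of 100 genes changed by 1 log2 unit were recovered. Of 100 changed by 2 units, 92 were recovered, and there were 7 false calls. The simulated genes were drawn independently, with a spread set by mean level alone and no GC trend between libraries. The rates may therefore differ in the real samples.

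Of 38 gene lists fixed before the data were examined, 36 were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists. The mitochondrial list had no measured gene, and the sex-linked list served only as a check. Camera with an estimated correlation and fry were alternatives. In simulation camera found the shifted list and called 0 of the unshifted lists. The simulated genes were drawn independently, so this could not show how camera at the preset correlation treats lists of correlated members.

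The genes named are the NMDA receptor subunits, up to 10 genes per direction with the largest change among those that passed with a mean of at least 1 CPM and no overlap between groups, members of the lists that passed over all genes or adjusted over the list alone, and up to 4 members with the smallest p in each list that passed. Unnamed loci and pseudogenes were counted and left out of this naming, and 1 gene that the rule names is not reported here. Hox genes outside this rule, Gm9493, Gm6166, Rps7, Acta1, Xist, the list members Dcn, Pdgfra, Lum and Apod, the genes at an FDR of 0.10 and the fast immediate early genes were chosen after their values were seen. So were the list members S100a8, S100a9, Ngp, Camp, Scn7a and Sox2.

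Alternatives covered the scaling, the filter, the test (DESeq2 1.42.0, limma-voom with and without quality weights, robust edgeR, limma on log2 of TPM plus 1), 1 surrogate variable from sva 3.50.0, leaving out each sample, haemoglobin and sex-linked genes, an FDR of 0.10 and a minimum log2 fold change of 1. The 6 separate libraries of the fixed design became an alternative. Alternatives chosen after seeing the data were DESeq2 on 6 libraries, the mean in place of the sum of libraries 5 and 6, and a GC correction by a lowess offset per library with a span of 0.3. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 prepared the tables.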

Results

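RNA was sequenced from lumbar dorsal root ganglia, the clusters of sensory neuron cell bodies and their glia beside the spinal cord. The series title places the deletion of Grin1, which encodes the obligatory GluN1 subunit of the NMDA receptor, in Schwann cells, the glia of peripheral nerve. The 3 wild-type libraries held 31827792, 32719517 and 28526704 expected counts, and knockout libraries 4, 5 and 6 held 28536700, 36249163 and 33219177. Between knockout libraries 5 and 6, 0 genes differed at an FDR of 0.05 by chi-square, with a mean chi-square per gene of 1.15 where simulated libraries of 1 RNA gave 1.01. They were counted as 1 sample, a choice made after this check, so n = 3 for wild type and n = 2 for knockout.

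**Figure D1:**
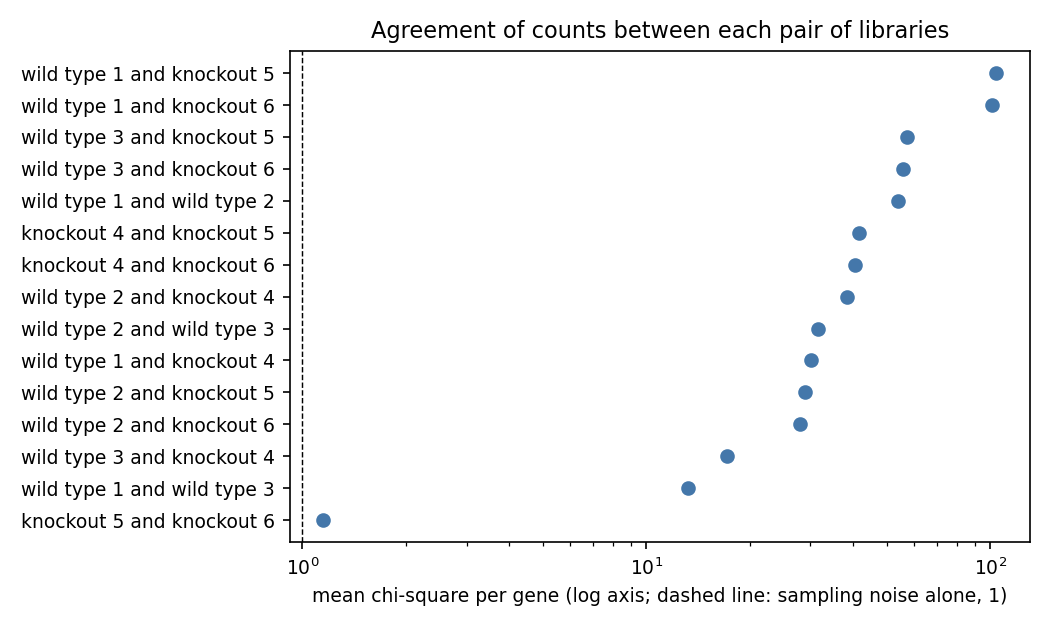
Mean chi-square per gene between the counts of each pair of the 6 libraries, on a log axis, with a dashed line at the value of sampling noise alone. The pair of knockout libraries 5 and 6 lies at 1.15 and the other 14 pairs lie between 13.2 and 104.0.

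The targeted gene was examined first. Grin1 (chromosome 2, 25291181 to 25319187, GRCm38) was at 86.3 ± 25.3 CPM (SD, n = 3) in wild type and 99.7 ± 24.8 CPM (SD, n = 2) in knockout. Its log2 fold change was 0.21 with a standard error of 0.26 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.812). By library, Grin1 was at 69.2, 112 and 74.1 CPM in wild type and at 81.7, 118 and 116 CPM in knockout libraries 4, 5 and 6. The whole ganglion includes neurons that keep the gene, so this level does not check the labels. Of the other measured subunits none passed: the log2 fold change was -1.11 for Grin2c, 0.27 for Grin2d, -0.18 for Grin3a and -0.20 for Grin3b, whose sign turned in 3 alternatives.

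The comparison of knockout with wild type asks how the deletion alters gene expression in the ganglion. The genes that rose most are known from sensory neurons with damaged axons. Sprr1a, a small proline-rich protein induced in regenerating neurons, rose from 0.485 ± 0.376 CPM (SD, n = 3) to 56 ± 8.11 CPM (SD, n = 2), a 112-fold difference. Atf3, a stress-induced transcription factor on chromosome 1 (191170296 to 191218039), rose 7.35-fold from 7.78 ± 1.26 to 57.3 ± 2.01 CPM. The neuropeptides Npy and Gal rose 55.1-fold and 3.82-fold. The genes that fell included the posterior homeobox genes Hoxd10 and Hoxd11 and genes used by subsets of sensory neurons, among them Th, the rate-limiting enzyme of catecholamine synthesis.

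In all, 16 of 16809 genes passed in the edgeR quasi-likelihood test, 10 higher and 6 lower in the knockout. With the 6 libraries counted separately 144 genes passed, 76 higher and 68 lower, among them all 16. At an unadjusted p under 0.05 there were 1537 of the 16809 genes, where chance alone gives a share of about 0.05. The groups did not overlap for 27.4% of genes, where chance gives 20%. The adjusted p from edgeR was 0.00722 for Atf3 and Gal and 0.00901 for Sprr1a.

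Further genes that rose were Cckbr, a cholecystokinin receptor, with a log2 fold change of 4.05 and a standard error of 0.39, and Ecel1, an endopeptidase-like protein of neurons, with 3.89 and 0.28. Fgf3, a fibroblast growth factor, rose by 3.89 on the log2 scale, from 7, 4 and 4 counts in the wild-type libraries to 70, 89 and 72 in the knockout libraries. Gpr151, an orphan receptor, rose 6.47-fold, Galnt6, a glycosyltransferase, 2.76-fold and Xdh, xanthine dehydrogenase, 2.16-fold.

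Among the genes that fell, Srd5a2, a steroid 5-alpha-reductase, had 124, 136 and 213 counts in wild type and 2, 4 and 2 in the knockout libraries. It lies on chromosome 17 from 74016955 to 74047916, near Xdh, which rose and lies from 73883895 to 73950196. Whether these 2 changes came from the deletion or from other differences between the animals was not tested. Hoxd11 fell from 6.23 ± 1.64 to 0.37 ± 0.0101 CPM, and Hoxd10 from 13.5 ± 1.46 to 1.35 ± 0.609 CPM. Both lie on chromosome 2, from 74679557 to 74687016 and from 74691924 to 74695105. Th fell 2.81-fold from 98.4 ± 10.6 CPM to 35 ± 0.00545 CPM, and Penk, the enkephalin precursor, 2.32-fold from 17.8 ± 0.677 to 7.67 ± 0.274 CPM. The sixth was the processed pseudogene Gm9493, with 541, 468 and 413 counts in wild type and 7, 0 and 0 in knockout. The knockout SDs of Th and Hoxd11 are over 2 samples, 1 of them the sum of libraries 5 and 6. In knockout libraries 4, 5 and 6, Th was at 34.8, 35.9 and 33.7 CPM and Hoxd11 at 0.375, 0.551 and 0.156 CPM. The expected counts of Hoxd10, Hoxd11, Penk, Galnt6 and Gm9493 were not whole, so RSEM shared part of their reads with other transcripts.

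Across the Hox family, whose paralog groups are numbered from anterior to posterior, the 25 measured genes of groups up to 9 lay between -0.47 and 0.55 on the log2 scale and none of them passed. In the posterior groups Hoxa10 was at -0.10, Hoxc10 at -0.24 and Hoxa11 at -0.44, and Hoxc11 had 30, 48 and 61 counts in wild type and 3, 1 and 4 in knockout (log2 fold change -4.09; edgeR quasi-likelihood adjusted p = 0.11).

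**Figure D2:**
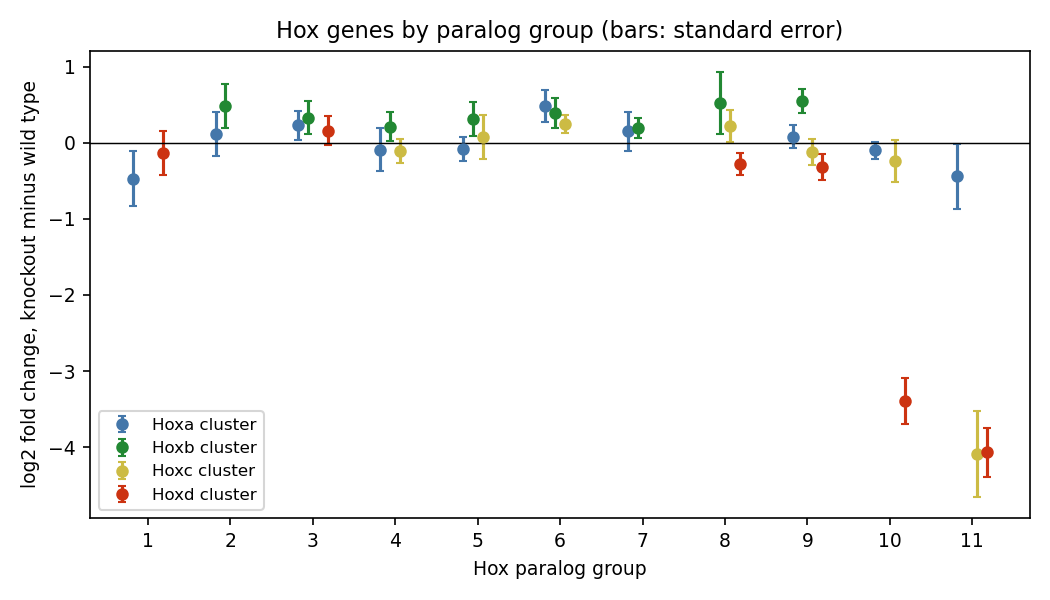
Log2 fold change of the 31 measured Hox genes, knockout minus wild type, against paralog group, coloured by cluster, with bars of 1 standard error. Hoxd10, Hoxd11 and Hoxc11 lie at -3.39, -4.07 and -4.09, apart from the rest.

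**Figure D3:**
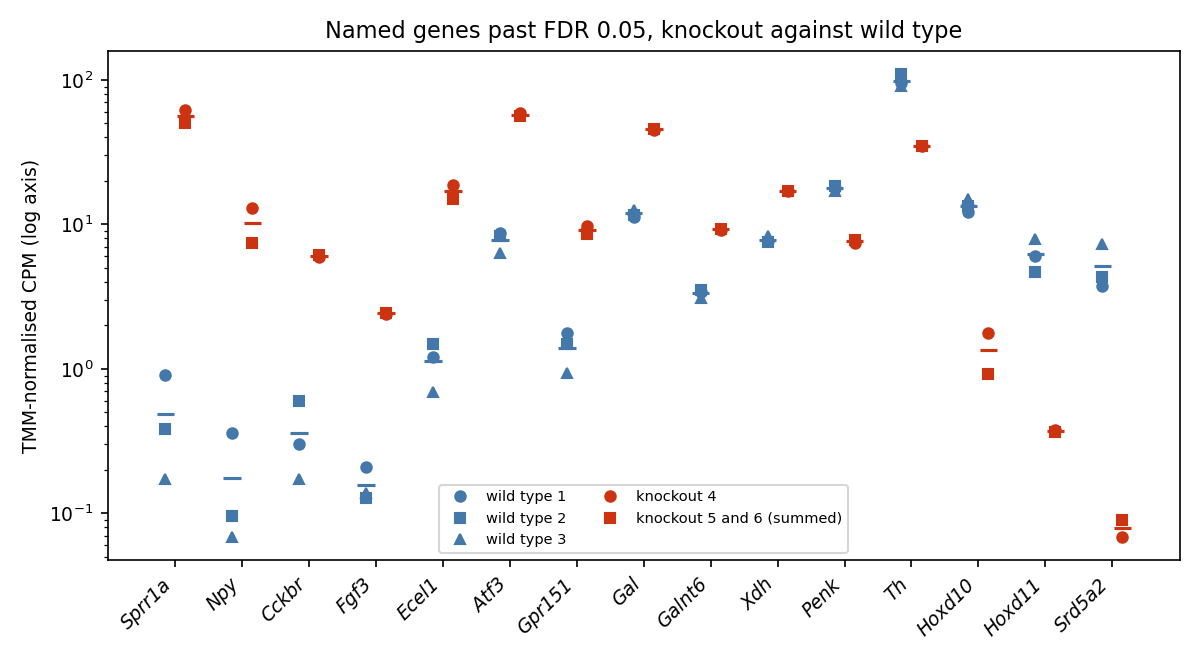
Level of each named gene that passed, in TMM-normalised CPM on a log axis, with 1 point per sample and a short line at each group mean (blue, wild type; red, knockout). Sprr1a lies below 1 CPM in each wild-type sample and at 61.7 and 50.3 CPM in the knockout samples, while Th lies at 94.6, 110 and 90.2 against 35 and 35 CPM.

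Leaving out 1 sample moved the count to 8 without wild type 2, to 10 without wild type 3 and to 7 without knockout 4. Atf3, Ecel1, Gal and Sprr1a passed whichever 1 sample was left out, while the other 11 named genes were each lost without at least 1 sample. Galnt6, Penk and Xdh were lost whichever sample was left out. Cckbr, Fgf3 and Gpr151 each kept the call in only 1 of the 5 omissions.

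Of the gene lists, 16 of 36 passed camera, 11 higher and 5 lower. The sensory neuron injury response stood out, with 21 of 21 measured members positive and a median log2 fold change of 1.20. By edgeR 7 of them passed over all genes and 18 adjusted over the list alone. Besides those above, Crh, corticotropin-releasing hormone, was at 4.28 on the log2 scale, Nts, neurotensin, at 2.08, Lmo7 at 1.40, Sema6a at 1.20, Sox11 at 1.06 and Csf1 at 1.02, each passing over the list alone. So did Stmn4, Hrk, Gadd45a, Flrt3 and Gap43, between 0.36 and 0.83. Its camera adjusted p was 2.2e-27, and it was 0.0422 with an estimated correlation. It was the only list that passed with an estimated correlation or with fry (adjusted p = 0.00275).

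Glial lists were higher by small amounts. Of 20 genes of myelin and myelinating Schwann cells 19 were positive with a median of 0.33, and 0 passed edgeR over all genes or adjusted over the list alone (camera adjusted p = 4.0e-07; adjusted p = 0.35 with an estimated correlation). The members with the smallest p were Gjb1, Ncmap, Egr2 and Fa2h. Satellite glia had 9 of 9 positive with a median of 0.29, and Kcnj10, an inward-rectifier potassium channel, and Fbln5 passed adjusted over the list alone (adjusted p = 0.305 with an estimated correlation). In repair Schwann cells, with a median of 0.35, Tnc, Bdnf and Gap43 passed adjusted over the list alone, of 12 measured members (adjusted p = 0.443 with an estimated correlation). Bdnf and Gap43 are also made by neurons. The Remak list, for the Schwann cells of unmyelinated axons, had 7 members positive and 2 negative, Scn7a at -0.27 and Sox2 at -0.03. Chl1 at 0.60 was the 1 of 9 to pass over the list alone, beside Gfap at 0.93 and Ncam1 at 0.32 (adjusted p = 0.305 with an estimated correlation). Of 12 genes of neuregulin and LRP1 signalling, Lgi4 at 0.76 and Erbb3 at 0.48 passed over the list alone (adjusted p = 0.305 with an estimated correlation).

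The fibroblast and extracellular matrix list had a median of 0.36. Of 18 members 14 were positive and 4 negative, and 9 passed adjusted over the list alone, all of them higher, among them Col1a1 at 0.61, Col3a1 at 0.63, Col5a2 at 0.66 and Fn1 at 0.99 (adjusted p = 0.522 with an estimated correlation). These encode matrix proteins. The fibroblast genes Dcn at -0.47, Pdgfra at -0.25, Lum at -0.15 and Apod at -0.12 did not pass. Endothelium had a median of 0.32 with Flt1 and Esam passing over the list alone, and bone and cartilage a median of 0.56 with Ibsp and Col2a1 (adjusted p = 0.305 with an estimated correlation for both lists). In the glucocorticoid list Cdkn1a, an inhibitor of the cell cycle, at 0.66 was the 1 of 9 to pass adjusted over the list alone, and 0 passed over all genes (adjusted p = 0.666 with an estimated correlation). Of 15 immediate early genes Egr3 at 1.12 passed adjusted over the list alone and 0 over all genes (adjusted p = 0.498 with an estimated correlation), and the list's call ended after GC correction (camera adjusted p = 0.094).

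Non-peptidergic and pruriceptive neurons, which carry itch and mechanical pain, were lower, with 16 of 20 members negative and a median of -0.36. By edgeR 8 fell adjusted over the list alone, among them Lpar3 at -1.09, Agtr1a at -1.04, Nppb at -0.97 and Mrgprd at -0.39, while Nts rose (adjusted p = 0.305 with an estimated correlation). In MHC class II the median was -0.53, and Cd74, H2-Eb1 and H2-Aa of 7 members fell over the list alone (adjusted p = 0.569 with an estimated correlation). Cholesterol synthesis had 14 of 17 members negative with a median of -0.11, and 0 passed (adjusted p = 0.305 with an estimated correlation). The mast cell and neutrophil list, with a median of -0.57, and the T and B lymphocyte list, with -0.40, had 0 members passing (adjusted p = 0.666 with an estimated correlation for both). In the former 6 members were negative, among them the mast cell genes Mcpt4 at -1.33 and Tpsb2 at -1.15. The 4 positive members were the neutrophil genes S100a8, S100a9, Ngp and Camp, at 0.12 to 0.17. The direction of both lists turned without knockout libraries 5 and 6.

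**Figure D4:**
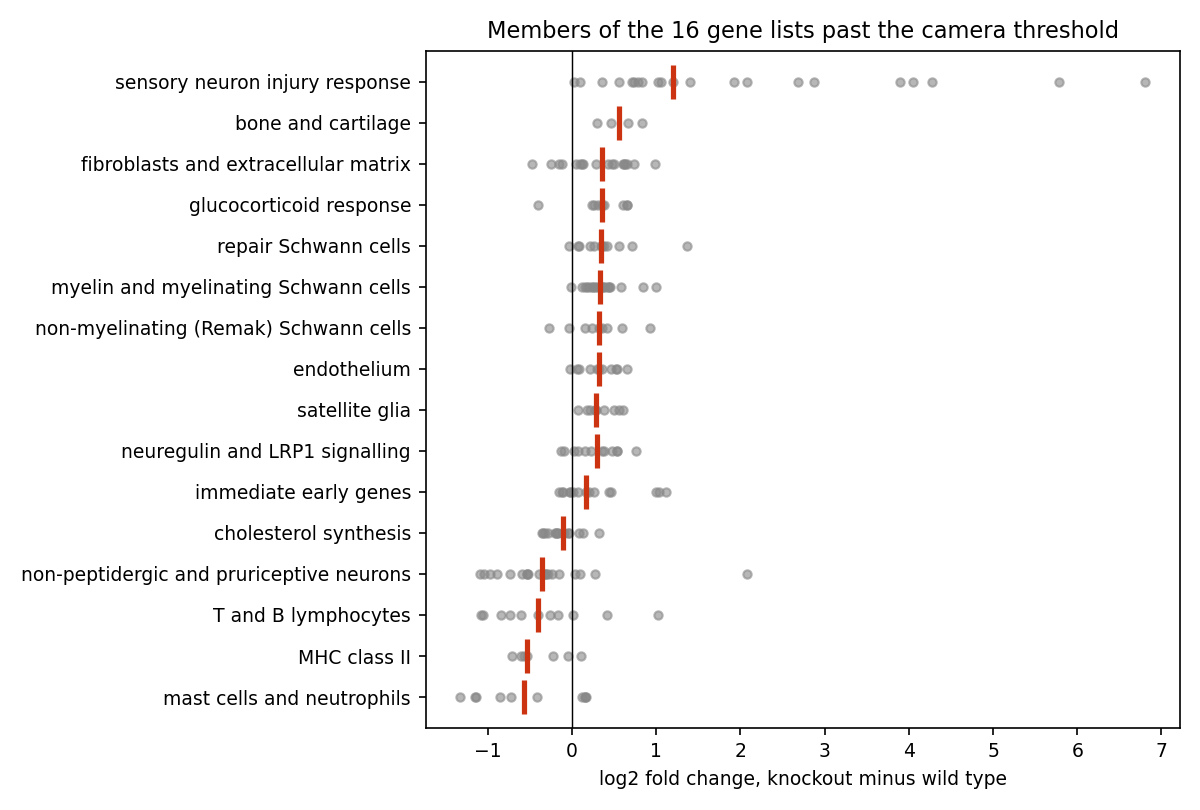
Log2 fold change of each measured member (grey points) of the 16 lists that passed camera, with the median as a red bar. The sensory neuron injury response has a median of 1.20, and the median of mast cells and neutrophils is -0.57.

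Other neuronal lists did not pass camera. Pan-neuronal genes had a median of 0.03 and peptidergic nociceptors 0.02. In the list of large-diameter and C-low-threshold neurons, with a median of 0.25, Th fell over all genes, and Slc17a8, the vesicular glutamate transporter 3, fell by 0.99 on the log2 scale adjusted over the list alone. Adjusted over the list of other glutamate receptors and transporters alone, Slc17a8 and Grik1, a kainate receptor subunit at -0.67, fell. Gabra3 at -0.62, a subunit of GABA type A receptors, fell adjusted over its list alone. Syt1 at -0.55 and Calcb at -0.52 fell over the pan-neuronal and peptidergic lists alone, and Bdnf at 0.56 rose over the peptidergic list alone. Over the list of mural cells alone Rgs5 at -0.79 fell, while Notch3 at 0.58 and Cspg4 at 0.71 rose. Knockout library 4 held 1.52% of its counts in haemoglobin genes against 0.304 to 0.598% in the other libraries. The erythroid and skeletal muscle lists did not pass camera (adjusted p = 0.054 and 0.174).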

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

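No paired analysis was possible because the mouse numbers 1 to 6 are not shared between the groups. The 6 separate libraries are the design fixed before the data were examined, while summing libraries 5 and 6, their mean, DESeq2 on 6 libraries and the GC correction were chosen after seeing the data. The count of 16 changed genes became 144 with the 6 libraries counted separately, 851 in DESeq2 with 6 libraries and 433 with GC correction and 6 libraries, where by construction the near-identical pair counts as separate animals. It became 81 with no filter, 246 with DESeq2, 27 with limma-voom and quality weights, 742 with 1 surrogate variable and 30 at an FDR of 0.10. The cause was not tested except at the FDR, where the looser threshold itself adds genes. Leaving out replicates gave 7 to 16 genes. The remaining alternatives gave 12 to 23. Lists past camera numbered 14 to 20 without single replicates, and 1 with an estimated correlation and 1 with fry, both of which allow for correlated members. Grin1 did not pass under any alternative. Its log2 fold change ranged from -0.07 without knockout replicates 5 and 6 to 0.47. Grin3b, at -0.20, turned to 0.01 on TPM, and with replicates left out ran from -0.73 (without knockout replicates 5 and 6) to 0.10, turning without wild type 3 and without knockout 4 (0.07). Dmp1, at 0.30, ran from -0.25 without knockout replicates 5 and 6 to 0.63, and was at -0.01 without wild type 1. The T and B lymphocyte and the mast cell and neutrophil lists turned without knockout replicates 5 and 6 (camera adjusted p = 0.878 and 0.933, and from 0.00346 and 0.00103 without other replicates). The cause was not tested for these. Of the other values of single genes, 2229 kept direction and side of the threshold, 51 lost the call and 224 gained it. Of those of lists, 256 kept both and 46 lost the call. Leaving out knockout 4, or 5 and 6 together, left 1 knockout sample, which was assumed to vary like the wild type. Depth limits Fgf3, Npy, Srd5a2, Crh, Hoxc11, Gm9493 and Gm2423, with at most 12 counts per library in their lower group. Crh had 0, 5 and 2 counts in the wild-type libraries and 44, 50 and 50 in the knockout libraries.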

Other observations

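All tests of explanations in this part were chosen after the results were seen, and some replaced or followed earlier tests, as stated where they appear.

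At an FDR of 0.10 in edgeR, 14 further genes were reached. Slc6a4, the serotonin transporter, was at 0.402 ± 0.225 CPM (SD, n = 3) in wild type and 4.67 ± 0.392 CPM (SD, n = 2) in knockout, and Fst, follistatin, at 1.9 ± 0.173 and 6.16 ± 0.76 CPM. Adam8, a membrane metalloprotease, Angptl2, Col5a3, a chain of type V collagen, and Smim3 were 1.9-fold, 1.94-fold, 1.74-fold and 2.19-fold higher. On the lower side were Acpp, an ectonucleotidase of non-peptidergic neurons, 1.83-fold, Fxyd2, a regulator of the sodium pump, 1.87-fold, Paqr5, 1.82-fold, and Gadl1, 2.59-fold. Their edgeR adjusted p lay between 0.0506 for Fst and 0.0982 for Fxyd2. The others were Lmo7, Slc17a8, Rps7 and the processed pseudogene Gm2423, with 66, 35 and 43 counts in wild type and 0, 0 and 0 in knockout.

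The injury genes were higher in both knockout samples, with a median log2 fold change of 3.89 over the 7 that passed. For these 7, a GC trend between libraries is argued against, since the median was 3.80 after GC correction and all 7 still passed. So is a larger share of neurons, since the highest pan-neuronal gene was at 0.23. The 7 were picked because they passed in these data. Neither check therefore covers the injury list members with smaller changes, the lowest of which was at 0.03. Acute handling stays open. The 15 immediate early genes had a median of 0.17, with 10 positive and 5 negative. The highest were Egr3 at 1.12, Arc at 1.04 and Egr2 at 1.00. The list passed camera, but not with an estimated correlation and not after GC correction (camera adjusted p = 0.094). An earlier test on Fos, Fosb, Junb, Egr1 and Ier2 alone (median 0.07) was set aside, since these were picked after their values were seen. An effect of the deletion, a nerve or skin injury in these mice and other differences between the animals stay open and were not tested.

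Of 6 Hox genes of group 10 or higher, Hoxd10 and Hoxd11 fell over all genes and Hoxc11 on chromosome 15, at -4.09 on the log2 scale, only adjusted over the Hox genes alone (edgeR adjusted p = 0.00224, and 0.11 over all genes), while Hoxa10, Hoxc10 and Hoxa11 at -0.10, -0.24 and -0.44 did not pass. The value of Hoxc11 argues against an interval linked to Grin1 on chromosome 2 as the whole cause. Ganglia from a more anterior segment could lower such genes, and the first test of this, the rank correlation of paralog group with log2 fold change across 28 Hox genes at 1 CPM or more, gave rho = -0.35 (permutation p = 0.066) and left it open. Then 2 further tests were run on the same genes, rho = -0.37 (permutation p = 0.042) across all 31 measured Hox genes and a Fisher's exact test of the 3 genes that fell adjusted over the Hox genes alone, among 6 of group 10 or higher, against 0 among 25 of lower groups (p = 0.00445). As they followed a test that did not decide and rest on the genes that raised the question, they do not settle it, and an effect of genotype stays open too.

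Knockout libraries 5 and 6 had a mean chi-square per gene of 1.15, and Gm6166 had 945 and 867 counts in them against 11 to 26 in the other libraries. Both libraries may come from 1 RNA sample, which is in line with the 0 genes differing in the chi-square test. A GC trend shared by different animals is argued against: after each pair's own GC trend was removed, the lowest of the other pairs was still at 11.8. This replaced a first test, the value of 28.9 between wild type 2 and knockout 5, which crossed genotypes and decided nothing. Pooling of RNA or tissue from both mice was not tested.

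Of 10 splits of the 5 samples, the real one gave 16 genes, the highest other 1125 and the next 4, so that 2 splits, the real one included, reached 16. With 6 libraries the real split gave 144, the highest other 2917 and the next 0, again 2 with the real one. The splits are too few for a share under 0.05. The highest other split in both sets wild type 2 with knockout libraries 5 and 6 against the rest, and points to a structure of the samples. It parts the libraries whose levels rose with GC content (rho = 0.41, 0.43 and 0.43 across genes) from those where they fell (-0.53, -0.43 and -0.25). After GC correction the 5 samples gave 23 genes in the real split and 4 in the highest other, while the 6 libraries gave 433 and 1530.

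Rps7 had 1589, 1181 and 1173 counts in wild type and 563, 615 and 520 in knockout. Acta1, of skeletal muscle, was at 8.28 CPM in knockout library 4 and at 0.4 to 2.72 CPM in the others. Xist had at most 8 counts in each library.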
